A study of Mus musculus with 6 samples.

How the data were processed

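RNA bound to HA-tagged ribosomes was measured in kidneys of neonatal mice. The labels give 3 littermate controls and 3 Foxp1-deficient animals' libraries, and groups and replicate numbers were taken from the sample titles. Nothing in the labels states that the replicates are separate animals, so p-values measure the spread between these libraries, which may be technical. The labels' treatment tag differs between the groups (vehicle for control, chronic acid load for Foxp1-deficient), the labels' protocols mention no acid load, and any difference between groups can belong to either.

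The deposited table holds raw counts of fragments per gene symbol, made by the authors with featureCounts 1.5.1 in paired mode over exons, with mm10 annotation version 86, per the file headers. The header's command has no strand option and no option to count multi-mapping reads, so a gene and its antisense partner cannot be told apart, and near-identical gene copies such as the globins are uncertain. FastQC, Trimmomatic, STAR, SAMtools, deepTools and DESeq2 are named per the submitters' processing notes, without versions or roles. Read trimming, alignment settings and filters are not given in the sources used here. The table has 48587 rows, all with a gene name, and each of its 6 count columns was matched to a sample by its name. The gene length column, deposited by the authors in bases, was not used in any test.

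Counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, which left 14311 genes. CPM given with mean ± SD for genes compared between genotypes are scaled by TMM, whereas CPM given per library and list medians use the library total. Gene lists were tested with camera of limma 3.58.1 on the edgeR fit with a preset correlation of 0.01, then with an estimated correlation and with fry, which asks whether a list's genes move, on balance, in the same direction and does not compare them with other genes. Tests were two-sided. Library totals ran from 9710048 to 18958196 counts, and 3 counts, the most that a count of 0 allows, correspond to 0.158 to 0.309 CPM. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.

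The design, the alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Foxp1, the 10 higher and 10 lower genes of largest fold change past the threshold with groups apart and at least 5 CPM in the higher group, or the 5 of lowest p where none passes, and up to 4 members of lowest p from each list described in detail. Predicted genes were left out of the ranking, and a gene that the rule takes is not reported here. The 12 lists described in detail were chosen after values were seen, as were the 13 further gene lists used for levels, the count of genes that differ alike in all pairs, and the alternatives that leave out the libraries numbered 2 or add a block to DESeq2 and limma-voom.

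The replicate numbers were checked for pairing before calls were compared. Deviations from group means of libraries with the same number correlated across genes at r = 0.57, 0.53 and 0.62 in pairs 1, 2 and 3, and the first principal component (56.4% of variance) set the libraries numbered 2 apart. The numbers were therefore taken to pair the libraries, from the data rather than from a statement in the labels, and a fit with the replicate number as a block stands beside the main one where it changes a call.

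The procedure was tested on simulated counts with the real libraries' means, sizes and pair structure, on 13541 genes of which 100 were changed 2-fold and 100 were changed 4-fold. The edgeR test without a block recovered 0% of both sizes, and with the block 25% and 82%. DESeq2 1.42.0 recovered 0% and 38% without a block, and 46% and 91% with one, and limma-voom with a block recovered 26% and 84%.

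Alternatives were other size factors (RLE, upper quartile, library totals), no or a stricter low-count filter, removal of sex-chromosome and mitochondrial genes or of erythroid, immediate-early and very abundant genes, DESeq2, limma-voom with quality weights, the replicate block, other list tests, and each library left out in turn. Input libraries were not analysed here. Figures were drawn with matplotlib in Python.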

Results

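Ribosome-associated RNA of neonatal mouse kidney was counted per gene in 6 libraries, 3 from littermate controls and 3 from Foxp1-deficient animals. Foxp1 encodes a forkhead transcription factor. The animals carried RiboTag, an allele that puts an HA tag on a ribosomal protein in cells with Cre activity, and Cre was driven by Cdh16, a cadherin gene of kidney tubule epithelium. Anti-HA beads recovered the tagged ribosomes with their RNA, and the 6 libraries were all such pulldowns. Controls were heterozygous for the floxed Foxp1 allele, and Foxp1-deficient animals were homozygous. The treatment label also differed between the groups, reading vehicle for the 3 controls and chronic acid load for the 3 Foxp1-deficient libraries, whereas the protocols described no acid load. By the labels, genotype and treatment therefore could not be separated. The comparison is between both groups of pulldown libraries, whichever cells their RNA came from.

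Total counts were 14281261, 11264609 and 18206881 in controls 1, 2 and 3, and 16820360, 9710048 and 18958196 in Foxp1-deficient libraries 1, 2 and 3. Genes with at least 1 count numbered 18241, 13885 and 21684 in the controls and 18876, 14285 and 22190 in the Foxp1-deficient libraries. Rn18s-rs5, Gm23935, Gm26917 and Lars2 were counted together as rows of ribosomal RNA type, although Lars2 is a protein-coding gene. Together they took 6.65% of counts in control 2 and 8.72% in Foxp1-deficient 2, against 1.49% to 2.85% in the other 4 libraries. Rn18s-rs5 alone took 4.245% and 4.69%, against 0.893% to 1.84%. Among genes averaging at least 10 CPM (counts scaled to a fixed library total) in the libraries with other numbers, 1.43% had no count in control 2 and 1.42% in Foxp1-deficient 2, and at most 0.151% in the other 4. The measures of library quality gave exact two-sided permutation p from 0.7 to 1 between genotypes, where 3 against 3 allows no p below 0.1. Within pairs of equal number, the Foxp1-deficient library had more genes detected and a lower share of genes at 0 in 3 of 3 pairs (exact paired sign-flip p = 0.25 for each, the smallest that 3 pairs allow).

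Foxp1 (chromosome 6, 98925338 to 99522721, mm10) had 38.5 ± 9.27 CPM in controls and 25.0 ± 12.2 in Foxp1-deficient libraries (SD, n = 3 each, CPM scaled by TMM). The log2 fold change was -0.62 (SE 0.49), within the spread between libraries in the fit without a block (unadjusted p = 0.246, adjusted p = 0.9998, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With the replicate number as a block it was -0.72 (SE 0.28, unadjusted p = 0.0496, adjusted p = 0.853, edgeR quasi-likelihood test). Foxp1 was lower in the Foxp1-deficient library of each of the 3 equally numbered pairs, by log2 differences of -0.49, -1.43 and -0.29. Without Foxp1-deficient library 2 the fold change was -0.27. Gene-level counts also take reads from exons left in the floxed allele and from cells without Cre, so they check the genotype only in part.

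Transcripts of the kidney tubule were unevenly represented among the libraries, in both genotypes alike. Umod, encoding uromodulin of the thick ascending limb, had 78.9 CPM in control 3 and 87.1 in Foxp1-deficient 3, and at most 0.773 in the other 4. Slc34a1, a phosphate transporter gene of the proximal tubule, had 121 and 125 CPM in the libraries numbered 3 and at most 9.68 in the others. Cdh16 itself had 0.35, 9.23 and 48.6 CPM in controls 1, 2 and 3 and 0.297, 1.96 and 48.5 CPM in Foxp1-deficient libraries 1, 2 and 3. The median CPM of the 20 proximal tubule genes was 0.21, 1.73 and 25.5 in the controls and 1.01, 0.721 and 26.3 in the Foxp1-deficient libraries.

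**Figure D1:**
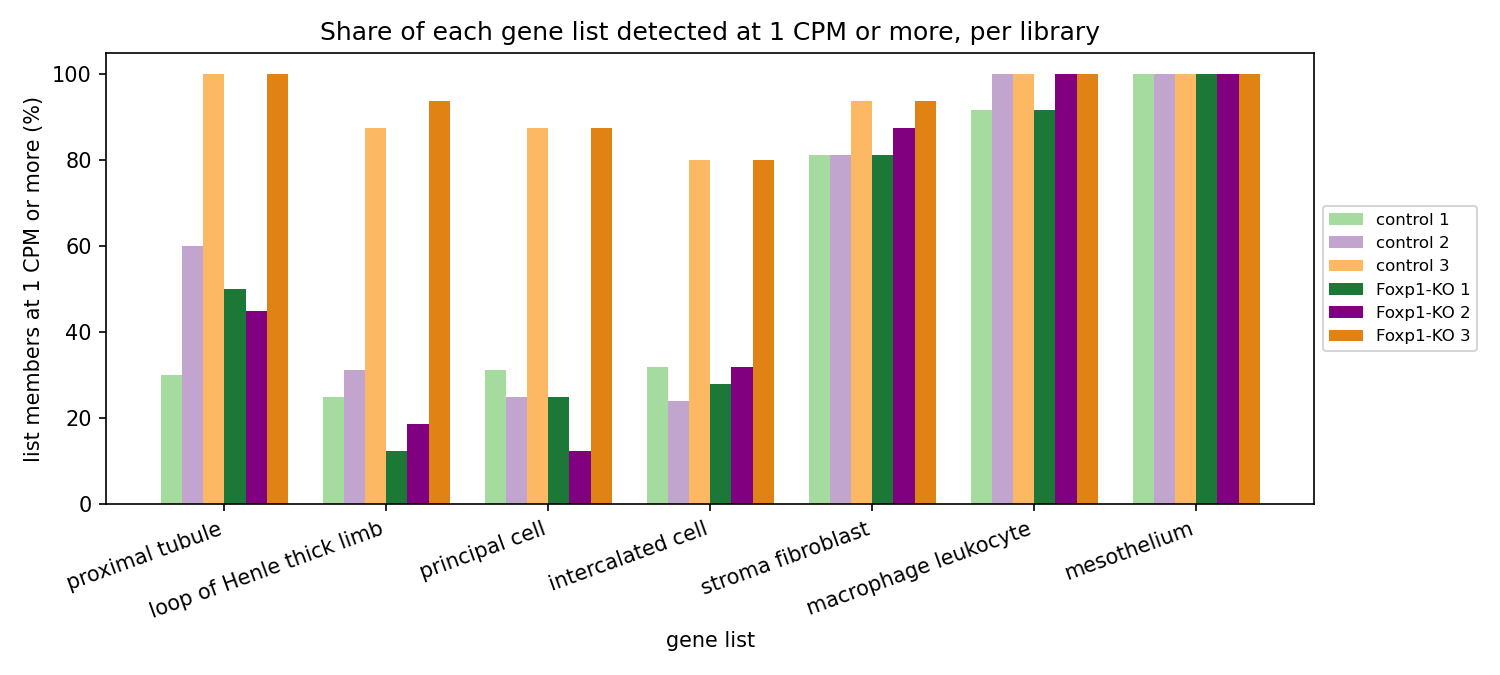
Share of the members of 7 gene lists that reached 1 CPM or more (y axis, percent) in each of the 6 libraries (bars, colour by library). All 20 proximal tubule genes reached 1 CPM in both libraries numbered 3, against 6 to 12 in the other 4, whereas all 14 mesothelium genes did so in every library.

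Stromal and mesothelial transcripts were abundant in all 6 libraries. Col1a1, a fibrillar collagen gene, ranged from 1743 to 10090 CPM. The median of the 16 stromal and fibroblast genes ranged from 44.4 to 163 CPM. Upk3b, a uroplakin gene also expressed by mesothelium, ranged from 596 to 2133 CPM, and Msln, encoding mesothelin, from 183 to 1288 CPM. Replicate number accounted for 69.5% of the variance of log2 CPM and genotype for 11.9%. With 6 libraries any grouping takes up a share of the variance, so 11.9% does not by itself show an effect of genotype.

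Between genotypes, no gene passed the test. The genes named here were the 5 of lowest p in each direction among those whose CPM did not overlap between groups and reached 5 in the higher group. Smpd3, encoding a neutral sphingomyelinase, had 40.8 ± 14.7 CPM in controls and 225 ± 20.9 in Foxp1-deficient libraries (SD, n = 3 each). Col6a2, a collagen VI chain gene, had 61.6 ± 5.63 and 254 ± 33.4 CPM, and Krt14, a basal keratin gene, 28.7 ± 9.26 and 204 ± 107. Map6, encoding a microtubule-associated protein, had 7.56 ± 4.11 and 41.6 ± 7.85 CPM, and Pltp, encoding phospholipid transfer protein, 9.78 ± 1.2 and 41.8 ± 18.3. The log2 fold changes of these 5 genes were 2.46 (SE 0.40) for Smpd3, 2.04 (SE 0.34) for Col6a2, 2.83 (SE 0.52) for Krt14, 2.45 (SE 0.50) for Map6 and 2.09 (SE 0.45) for Pltp. In the other direction, Mpo, encoding myeloperoxidase of granulocytes, had 6.56 ± 4.27 CPM in controls and 0.344 ± 0.446 in Foxp1-deficient libraries. Sprr2k had 10.6 ± 8.73 and 1.34 ± 0.395 CPM, Mfap4, a microfibril protein gene, 144 ± 42.9 and 61.5 ± 17.1, Kcne1l 128 ± 64.7 and 35.7 ± 25.0, and Dpep1, a dipeptidase gene, 59.1 ± 24.7 and 23.8 ± 7.88. All 10 genes differed in the same direction in each of the 3 pairs, which the choice of genes without overlap between groups fixed in advance.

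**Figure D2:**
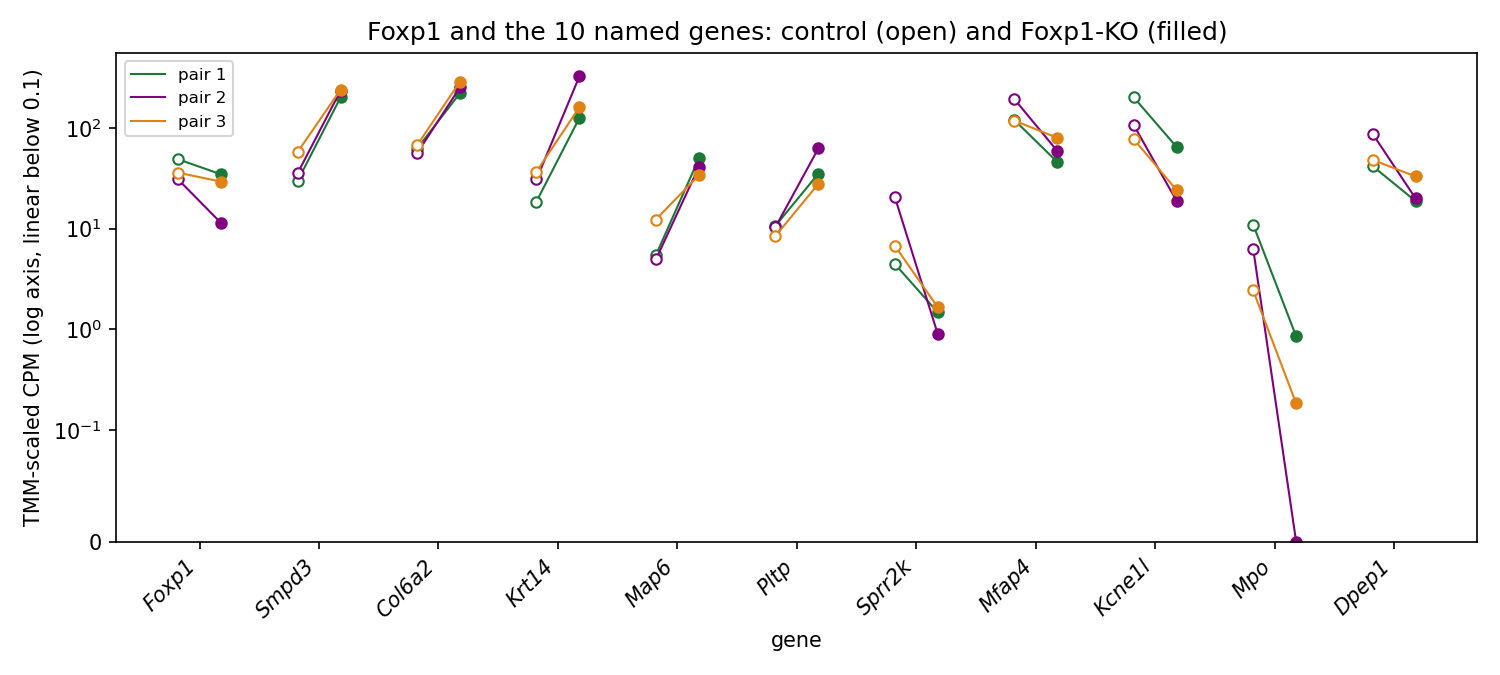
TMM-scaled CPM (y axis, log scale, linear below 0.1) of Foxp1 and 10 named genes in the 3 control (open circles) and 3 Foxp1-deficient (filled circles) libraries, with lines joining libraries of the same number. The 10 are the 5 of lowest p in each direction among genes whose groups did not overlap. Each line of Smpd3 and Col6a2 runs upward, from group means of 40.8 and 61.6 CPM in controls to 225 and 254 CPM, and each line of Foxp1 runs downward; none of the 11 genes passed the test.

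Of 14311 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower in Foxp1-deficient libraries at an adjusted p under 0.05, and 103 had an unadjusted p under 0.05, where about 716 would by chance. DESeq2 called 6 genes, all higher in Foxp1-deficient libraries: Col6a2, Smpd3, Krt14, Map6, Efemp1 and Serpinb1a, of which Efemp1 and Serpinb1a were named after their values were seen. limma-voom with quality weights called 0, with 330 at an unadjusted p under 0.05. With the replicate number as a block, edgeR called 0 genes, with 762 at an unadjusted p under 0.05 and a lowest adjusted p of 0.192. Alternatives chosen after seeing the data gave 171 calls with DESeq2 and a block and 244 with limma-voom and a block. Leaving out both libraries numbered 2 gave 30 calls in edgeR with a block and 0 without one. In simulated data that kept the spread between pairs, the test without a block recovered 0% of genes changed 4-fold, so its count of 0 does not show that genes were unchanged. In the same simulation 59 of 196 calls of DESeq2 with a block were false, against 10 of 117 for edgeR with a block and 10 of 120 for limma-voom with a block.

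Genes of macrophages and leukocytes fell as a list in Foxp1-deficient libraries by camera on the edgeR fit with a preset correlation (adjusted p = 9.6e-08). The call was lost with an estimated correlation (adjusted p = 0.957 with an estimated correlation) and in fry (adjusted p = 0.999). The correlation was estimated at 0.80 for this list, or 0.52 with the replicate block, against the preset 0.01. The p with the preset correlation thus takes genes that vary together as nearly independent. The call was also lost when Foxp1-deficient library 1 was left out. All 12 measured members were lower, with a median log2 fold change of -1.06. Beside them, 7 of 11 endothelial genes were lower and 4 higher, with a median of -0.89, and that list did not pass camera (adjusted p = 0.345), although it did in 5 of 21 settings. Of the 21, 4 were chosen after seeing the data (the libraries numbered 2 left out, with and without a block, and DESeq2 or limma-voom with a block). All 21 kept the preset correlation. Csf1r, the receptor gene for macrophage colony-stimulating factor, had 110 ± 66.6 CPM in controls and 45.5 ± 40.3 in Foxp1-deficient libraries (SD, n = 3 each). Adgre1, encoding F4/80, had 41.3 ± 21.2 and 17.9 ± 15.7 CPM, Laptm5 50.2 ± 17.1 and 21.9 ± 16.6, and Lyz2, encoding lysozyme, 213 ± 198 and 72.8 ± 73.5. None of the 12 genes passed over all genes tested, and 0 passed adjusted over the list alone. With the replicate block 4 passed adjusted over the list alone, and the median was -1.38.

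The urothelium list, with 4 tested members of 10, rose in Foxp1-deficient libraries by camera on the edgeR fit with a preset correlation (adjusted p = 5.07e-04). The call was lost with an estimated correlation (adjusted p = 0.885 with an estimated correlation) and in fry (adjusted p = 0.999). The correlation was estimated at 0.25 for this list, against the preset 0.01. The call was also lost when Foxp1-deficient library 2 was left out. Upk1b had 284 ± 52.0 CPM in controls and 595 ± 56.0 in Foxp1-deficient libraries (SD, n = 3 each). Upk3b had 780 ± 251 and 1515 ± 974 CPM, and Krt7 422 ± 350 and 1121 ± 1203. Upk1a was near the floor, with 0.211 ± 0.365 and 0.882 ± 0.965 CPM. Upk1b, Upk3b and Krt7 are also expressed by mesothelium, and the other 6 members of the list were too low to test. No member passed over all genes, and 0 passed adjusted over the list alone, or 3 with the replicate block.

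Cell cycle and oxidative phosphorylation genes passed camera on the edgeR fit with the replicate block (adjusted p = 0.0374 and 0.00238) and not without it (adjusted p = 0.276 for each list). Both calls with the block were lost with an estimated correlation (blocked adjusted p = 0.766 and 0.737 with an estimated correlation). Over 21 settings, the cell cycle list passed camera with a preset correlation in 6 and the oxidative phosphorylation list in 9. Of 24 cell cycle genes, 20 were lower in Foxp1-deficient libraries, with a median log2 fold change of -0.08. Mcm7, a subunit gene of the replicative helicase, had 234 ± 63.4 CPM in controls and 170 ± 37.4 in Foxp1-deficient libraries (SD, n = 3 each), Mcm3 158 ± 27.7 and 130 ± 30.6, Cdk1 181 ± 48.1 and 149 ± 35.6, and Bub1 58.8 ± 12.3 and 44.0 ± 20.7. Of 23 oxidative phosphorylation genes, 17 were lower, with a median of -0.18. Ndufa4 had 218 ± 136 and 140 ± 62.4 CPM, Atp5c1 203 ± 27.7 and 165 ± 7.24, Cyc1 144 ± 19.7 and 121 ± 5.04, and Tfam, a mitochondrial transcription factor gene, 44.6 ± 6.11 and 35.2 ± 13.9. The blocked fry test passed for oxidative phosphorylation (adjusted p = 0.0437) and not for cell cycle (adjusted p = 0.293).

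Stromal and matrix genes went both ways, and neither list passed camera on the edgeR fit (adjusted p = 0.694 and 0.325). Over the 21 settings the stromal list passed in 0 and the matrix list in 7, each time higher in Foxp1-deficient libraries. Of 15 stromal genes, 7 were higher and 8 lower. Acta2, the smooth muscle actin gene, had 7230 ± 1904 CPM in controls and 3621 ± 1886 in Foxp1-deficient libraries (SD, n = 3 each). Pdgfrb, a pericyte receptor gene, had 39.6 ± 16.0 and 19.9 ± 7.64 CPM, Tcf21 109 ± 29.8 and 66.8 ± 6.45, and Dcn, encoding decorin, 271 ± 96.7 and 470 ± 246. Of 18 extracellular matrix and basement membrane genes, 15 were higher and 3 lower, with a median log2 fold change of 0.27, against 11 and 7 with a median of 0.10 in the fit with the replicate block. Lamb2, a laminin chain gene, had 63.1 ± 17.2 and 141 ± 46.3 CPM, Hspg2, encoding perlecan, 634 ± 182 and 1011 ± 142, Agrn, encoding agrin, 72.2 ± 31.2 and 114 ± 45.7, and Lama1 10.5 ± 7.15 and 3.32 ± 3.88. With the replicate block 3 genes of each list passed adjusted over the list alone, against 0 without it.

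Tubular injury genes were higher for 9 of 15 and lower for 6 (camera on the edgeR fit, adjusted p = 0.276), with 6 higher and 1 lower in all 3 pairs, and the list passed as higher in 4 of the 21 settings. Krt8 had 236 ± 74.9 CPM in controls and 590 ± 183 in Foxp1-deficient libraries (SD, n = 3 each), and Krt18, encoding its keratin partner, 240 ± 187 and 355 ± 224. Cd44 had 42.4 ± 13.8 and 66.4 ± 21.1 CPM, and Krt20 1.47 ± 1.43 and 4.75 ± 0.963. With the replicate block 1 injury gene passed adjusted over the list alone. Scaled to library totals, Krt8 had at least 194.8 CPM and Krt18 at least 129 CPM in each library, also in those with few tubule transcripts. The cells that these keratins came from are therefore open. Of 9 ureteric bud tip genes, 3 were higher and 6 lower (adjusted p = 0.677, camera on the edgeR fit). Wnt11 had 122 ± 22.9 and 69.7 ± 20.2 CPM, Etv5 49.9 ± 7.85 and 39.5 ± 8.04, and Etv4 43.6 ± 24.9 and 31.2 ± 8.93. Ret and Gfra1 of the same list reached at most 1.96 and 1.32 CPM in any library, scaled to library totals. Whether Wnt11, Etv5 and Etv4 came from ureteric bud tips is therefore open.

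None of the collecting duct and acid-base lists passed camera with all 6 libraries, and many of their genes lay near the detection floor. With a library left out, camera with a preset correlation called the principal cell list lower without control 2 (adjusted p = 0.0182) and without Foxp1-deficient 3 (adjusted p = 0.00134). Without control 3 it called the intercalated cell list (adjusted p = 0.0178) and the acid-base list (adjusted p = 0.0323) higher. Of 25 intercalated cell genes 12 could be tested, with 8 higher and 4 lower (camera on the edgeR fit, adjusted p = 0.485). Kit had 4.33 ± 0.66 CPM in controls and 2.88 ± 0.429 in Foxp1-deficient libraries (SD, n = 3 each), Tfcp2l1, a transcription factor gene of collecting duct cells, 9.29 ± 8.53 and 18.9 ± 14.6, Insrr 2.77 ± 2.61 and 0.627 ± 0.58, and Hepacam2 0.626 ± 0.608 and 2.04 ± 2.11. Of 9 principal cell genes tested, 4 were higher and 5 lower (camera on the edgeR fit, adjusted p = 0.276). Aqp2, the vasopressin-regulated water channel gene, had 4.5 ± 3.74 and 2.78 ± 4.81 CPM, Hsd11b2 3.78 ± 1.44 and 2.03 ± 3.13, Aqp4 0.92 ± 0.949 and 0.598 ± 0.803, and Apela 84.6 ± 30.2 and 56.4 ± 28.0. Of 21 genes for subunits of the vacuolar proton pump, 12 were higher and 9 lower (adjusted p = 0.821, camera on the edgeR fit), among them Atp6v1d with 72.7 ± 20.3 and 49.1 ± 3.11 CPM, Atp6v0e2 with 7.35 ± 4.57 and 16.1 ± 13.9, Atp6ap1 with 109 ± 12.1 and 140 ± 43.5, and Tcirg1 with 33.2 ± 19 and 49.7 ± 44.6. Of 19 acid-base transport and ammonia genes, 13 were higher and 6 lower (adjusted p = 0.577, camera on the edgeR fit), with 6 higher and 0 lower in all 3 pairs. Slc26a6 had 3.52 ± 1.34 and 9.25 ± 10.9 CPM, Slc4a2 80.8 ± 21.6 and 122 ± 76.7, Slc38a3 3.02 ± 2.03 and 1.68 ± 1.45, and Slc12a7 47.5 ± 2.86 and 38.4 ± 18. The direction of several of these genes turned when the libraries numbered 2 were left out or another tool was used: Slc26a6, for example, went from 1.38 to -0.52 on the log2 scale without those libraries.

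None of the other 14 lists passed camera on the edgeR fit, with adjusted p from 0.345 to 0.897. Over the 21 settings the proximal tubule list passed in 4, in opposite directions: lower without control 1 (adjusted p = 0.0205 by camera) or Foxp1-deficient 3 (adjusted p = 0.00376), and higher without control 3 (adjusted p = 1.88e-04) or without the libraries numbered 2 in a fit with a block (adjusted p = 0.00634). The erythroid list passed as higher in 3, and the thick limb and steroid response lists as lower in 1 each, without Foxp1-deficient 3. Among nephron lists, the thick limb had 5 genes higher and 4 lower, the distal convoluted tubule 5 and 4, the proximal tubule 5 and 9, podocytes 4 and 8, and nephron progenitors 1 and 5. Endothelial genes were higher for 4 and lower for 7, and erythroid genes for 9 and 2. Among pathways, Notch genes were higher for 8 and lower for 4, Wnt targets for 5 and 6, steroid response genes for 6 and 5, cilia and cyst genes for 11 and 7, immediate-early genes for 13 and 3, p53 and apoptosis genes for 5 and 11, and Fox family genes for 8 and 8. With the replicate block the tallies of higher and lower genes turned for the proximal tubule (5 and 9 to 9 and 5, median -0.11 to 0.16), the thick limb (5 and 4 to 3 and 6), cilia and cyst genes (11 and 7 to 7 and 11) and steroid response genes (6 and 5 to 4 and 7). Without the block, the sign of the median and of the test differed for the thick limb, proximal tubule, Notch, steroid response, cilia and Fox lists, with medians of 0.07, -0.11, 0.02, 0.02, 0.05 and 0.07.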

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

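The added alternatives (libraries numbered 2 left out, and a replicate block in DESeq2 or limma-voom) were chosen after seeing the data. The count of 0 genes held under RLE, upper-quartile and library-total scaling, both low-count filters, both gene exclusions, limma-voom with quality weights, the replicate block and each library left out, with 47 to 762 genes at an unadjusted p under 0.05. Exceptions were DESeq2 with 6 genes (6 higher), DESeq2 with replicate block with 171 (116 higher, 55 lower), limma-voom with replicate block with 244 (180 higher, 64 lower), and libraries numbered 2 left out with replicate block with 30 (28 higher, 2 lower). The coefficient of variation between libraries that edgeR estimated was 0.727 without the block and 0.397 with it. In other groupings of the libraries that part every pair, the same blocked fits called at most 2 genes with DESeq2 and 0 with limma-voom. Such groupings turn a difference shared by all pairs into spread, so these counts do not measure a rate of false calls. Otherwise the cause of these exceptions was not tested. Foxp1 stayed below 0 in all settings, from -0.93 without Foxp1-deficient replicate 1 to -0.27 without Foxp1-deficient replicate 2, with -0.72 under the replicate block, and passed in none.

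The macrophage list passed camera in 20 of 21 settings, not without Foxp1-deficient replicate 1, and the urothelium list in 20, not without Foxp1-deficient replicate 2. All 21 settings kept the preset correlation of 0.01, so these tallies do not bear on that assumption. The count of 2 gene lists became 4 with the replicate block, 7 with limma-voom with quality weights, 7 with libraries numbered 2 left out and 9 with the block as well, 5 with DESeq2 and a block, 6 with limma-voom and a block, and 0 with camera with estimated correlation and 0 with fry. With single libraries left out it ran from 1 to 7, at 1 without Foxp1-deficient replicate 1 and 7 without control replicate 3 or Foxp1-deficient replicate 3. The replicate block in edgeR changed no call of a gene over all genes tested.

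Signs turned for 10 named genes, none of which passed in the main test, and the cause was not tested. With limma-voom with quality weights the log2 fold change was -0.98 for Hepacam2, -0.32 for Slc26a6, 0.058 for Slc38a3 and -0.13 for Tcirg1. With libraries numbered 2 left out it was 0.22 for Aqp2, 0.062 for Slc12a7, -0.52 for Slc26a6, 0.08 for Slc38a3 and -0.22 for Tcirg1, and with the replicate block as well -0.87 for Hepacam2, 0.062 for Slc12a7, -0.54 for Slc26a6, 0.31 for Slc38a3 and -0.12 for Tcirg1. With limma-voom with replicate block it was 0.069 for Aqp2, -0.12 for Slc26a6 and -0.067 for Tcirg1. With single libraries left out the ranges were -0.76 to 0.074 for Etv4, -2.54 to 0.47 for Aqp4, -0.062 to 1.41 for Krt18, -0.57 to 0.04 for Slc12a7, -0.24 to 1.82 for Slc26a6, -0.056 to 0.84 for Slc4a2 and -0.40 to 1.03 for Tcirg1. Depth limits genes near 0.158 to 0.309 CPM, where most collecting duct genes of the libraries numbered 1 and 2 lie.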

Other observations

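Tests chosen only after their result was seen were those of gene loss through low complexity across all kinds of genes, of pulldown background, of a common kidney source, of fewer macrophages and of splits for the count of genes, together with the count of genes that differ alike in all pairs and the demand for a median of 5 CPM from posterior Hox genes. The embryonic globin genes Hbb-y and Hba-x were more abundant than the adult beta globin genes Hbb-bs and Hbb-bt in each of the 6 libraries, whose labels give neonatal animals. Hbb-y, the embryonic epsilon globin gene, had from 433 to 2624 CPM, and Hba-x, the embryonic zeta globin gene, from 164 to 1544 CPM. Hbb-bh1, also embryonic, had from 9.5 to 463 CPM and was below Hbb-bs in controls 2 and 3 and Foxp1-deficient 3. Hbb-bs had from 20.3 to 107 CPM and Hbb-bt from 15.3 to 62.5 CPM, while the adult alpha globin gene Hba-a1 had from 191 to 963 CPM. Globin copies share sequence, so these values are uncertain. Ccm2 had 9003 CPM in control 1 and from 26.9 to 62.1 CPM in the other 5 libraries. Xist, from 12.4 to 106 CPM, and the Y-linked Ddx3y, from 4.74 to 62.9 CPM, were both present in each library. Xist marks female and Ddx3y male cells, so it is open whether each library pools animals of both sexes, and n and SD count libraries rather than animals. List medians stayed at or below 1.58 CPM in each library for lung epithelium, intestine epithelium, keratinocyte and skeletal muscle genes, and ran from 0.712 to 3.64 CPM for neuron and glia genes and from 1.96 to 21.2 CPM for hepatocyte genes.

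Among 10684 genes averaging at least 5 CPM, 68 differed at least 2-fold in the same direction in all 3 pairs, 50 higher and 18 lower in Foxp1-deficient libraries. Exchanging the genotypes within 1 pair gave 3, 6 and 4 such genes. For the test across all genes, edgeR called 0 in the real split and at most 0 in the other 9 of the 10 splits of the 6 libraries, and all 10 splits gave as many. For gene lists the real split called 2 and the highest other split 13, and 7 of the 10 splits called as many as 2. With 10 splits no share under 0.05 can be reached. The splits that part all 3 pairs, as the real one does, called at most 3 lists, whereas the others keep 1 pair together on each side and follow the large spread between replicate numbers. Among those 4 splits, DESeq2 with a block called 171 genes in the real one and at most 2 in the others, and limma-voom with a block 244 and 0. With 4 such splits no share under 0.05 can be reached, which also holds for the exchange of genotypes within 1 pair. Exchanging 1 pair also turns a difference shared by all pairs into spread, so the low counts do not measure a rate of false calls. DESeq2 without a block called 6 genes in the real split, 0 in each of the other 3 splits that part all pairs, and from 74 to 712 in the 6 splits that keep a pair together, which points to the structure of the replicate numbers.

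The first pattern is that kidney tubule genes lay near the floor in the libraries numbered 1 and 2. In both libraries numbered 1, 45.2% of 42 tubule genes (19) fell under 1 CPM, against 0.569% of 9316 other genes. As they stand, these shares argue against loss of all kinds of genes alike there. The other genes were not matched for level, however, and include very abundant ones, such as Col1a1 with 10090 CPM in control 3. Such genes are less likely to fall under 1 CPM, so the contrast is weaker than the shares alone show. Fisher's exact p of 2.03e-30 takes genes that vary together as independent, so it does not measure replication over libraries. The tubule genes are also those in which the pattern was seen, so these shares restate it in part. The test of low complexity fixed beforehand left low complexity open. The share of genes at 0 was at least 3.85 times that of the libraries numbered 3, where over 5 was set. These shares rest on 14 and 4 genes at 0 in control 1 and Foxp1-deficient 1, against 1 and 0 in control 3 and Foxp1-deficient 3. The genes counted include tubule genes, such as Umod and Slc34a1, both at 0 in control 1. The measure therefore repeats the pattern in part and cannot decide on complexity. Cells from outside the posterior trunk stay open: 6 of 9 posterior Hox genes reached 1 CPM in each library numbered 1, which met the bound set against them, but that bound was wrong in asking only for presence, since medians of 2.52 and 1.37 CPM can come from a minor share of cells, 1 of 9 reached 1 CPM in each library numbered 2, and 1 and 2 of 8 kidney lineage genes did so in the libraries numbered 1 against 7 and 6 in those numbered 3. Whole-kidney background also stays open, since its test, a proximal median of at most 3.97% of that in the libraries numbered 3, measures the pattern again. So does a common source of kidney RNA in both libraries numbered 3, whose counts over 73 tubule genes spread 3.86 times counting noise, above the bound of 2 set for it yet below each of 1000 matched gene sets (lowest 3.96, median 8.80), and no biological explanation was tested because both genotypes show the pattern.

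The second pattern is the abundance of mesothelial and stromal transcripts. Mesothelial cells in the pulldown are a candidate source, since 13 of 14 mesothelium genes not looked at before reached 5 CPM in the 4 libraries numbered 1 and 3, although kidney stroma also expresses some of them. Heart tissue cannot be told apart from other sources: the median of 14 cardiomyocyte genes was 9.04 CPM in Foxp1-deficient 1 and 16.6 CPM in control 1, not both at 10 or above and not both under 1, the bounds set beforehand. Actc1 had 963 and 672 CPM in control 1 and Foxp1-deficient 1 and Myl7 688 and 446 CPM, while Ttn had 3.22 and 3.92 CPM. In control 2 and Foxp1-deficient 2 the list median was 17.8 and 6.64 CPM, and in control 3 and Foxp1-deficient 3 it was 3.38 and 12.6 CPM. Over these libraries, in the same order, Myl7 had 4363, 2878, 680 and 719 CPM and Actc1 213, 61.5, 115 and 77.4 CPM. The anti-HA pulldown would remove RNA of cells without tagged ribosomes, to an extent not measured here.

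The third pattern, picked after values were seen and with no gene past the main test, is that 7 of 9 tested keratin genes (Krt7, Krt8, Krt14, Krt18, Krt19, Krt20 and Krt80), Upk1b and Upk3b had more CPM in the Foxp1-deficient library of each pair and 9 of 12 macrophage genes fewer. Krt10 and Krt17 differed in both directions among the pairs, no list of keratins was tested, and Krt10 and Krt20 were low. A larger share of mesothelial cells that raises their genes alike did not reach the bound set for it. The 14 mesothelium genes had a median blocked log2 fold change of 0.16, where at least 0.5 was set. Krt19 belongs both to these 14 and to the 7 keratins of the pattern, so that gene is no separate test. Of the 14, 8 were above 0, with values from -1.21 for Rspo1 to 1.08 for Gpm6a, 1.13 for Msln and 1.46 for Krt19. The 95% bootstrap interval of -0.11 to 0.47 resampled genes rather than libraries, so it leaves out the spread between libraries. The 14 genes thus did not rise alike, and a larger mesothelial share as part of the account stays open. Fewer macrophages may account for the macrophage part, since 12 of 12 genes were below 0 in the blocked fit, from -1.82 to -0.48, but this restates the list from which the pattern was seen. Loss of Foxp1 and the acid load named in the labels both stay open and untested, since they fall on the same libraries.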
